A study of Arabidopsis thaliana with 666 samples.

How the data were processed

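RNA was measured by sequencing of poly(A) libraries, non-stranded per the labels, from 666 samples of whole Arabidopsis seedlings. Per the submitters' processing notes the tools were bcl2fastq 2.20.0, FastQC, Trimmomatic, HISAT2, featureCounts and Subread with the TAIR10 build, without their settings. The deposited values were raw read counts per gene, as whole numbers with a different total in each library, for 27206 nuclear genes and no chloroplast or mitochondrial gene. Of these 1170 had no count in any library and 26719 carry the same identifier in the TAIR10.1 annotation, from which symbols and positions were taken. Total counts per library ran from 1656231 to 12775440 with a median of 3501427, and no library was below the planned minimum. Counts come from reads without molecular identifiers, so no counting interval is given and precision rests on the spread between libraries.

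Samples were grouped by the labelled bacterial condition, treatment (mock or flg22) and experiment (e1 with 218 libraries, e2 with 222, e3 with 226). In No bacteria flg22 of e2 the same replicate number is given to more than 1 library, and all were used. Replicate numbers were not taken as pairs. The comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, except where a choice is said to have been made after.

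Counts were normalised with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 (trended dispersion, robust fit) in R 4.3.3. Low counts were filtered with filterByExpr and p-values adjusted by Benjamini-Hochberg to 0.05 over the genes tested. The experiment was an additive block in each fit. No term let an effect vary between experiments, so SE and adjusted p rest on the spread between libraries. They do not measure the spread between experiments. For flg22 against mock each condition was fitted on its own libraries. For each condition against No bacteria, and for its interaction with flg22, the condition was fitted with No bacteria. SynCom35 and HK-SynCom35 were fitted together on e2 and e3. The average over 34 strains and each strain against the mean of the other 33 came from joint fits of all strain libraries, with the dispersion trend estimated from 3000 genes and the tests' reduced models started at the full model's coefficients, which was checked to give near-identical p-values. DESeq2 1.42.0 with its own size factors was run for flg22 against mock in 4 conditions. CPM (counts scaled to equal library size) are given as mean and SD over libraries, and log2 fold changes with their SE.

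The 20 lists held 285 entries for 281 genes. A list was tested with camera (limma 3.58.1, preset correlation 0.01, prior count 2) and again with an estimated correlation, adjusted over the 20 lists. Members called over all genes and adjusted over the list alone were counted. List levels and response sizes per library were mean log2(CPM + 1) values. They were compared between a condition and No bacteria with a two-sided exact permutation test that enumerated all reassignments within experiment and treatment. Its p likewise rests on single libraries and does not measure the spread between experiments. The planned genes for the response size were those called in the same direction in a fixed share of the other conditions. As these were so few, the fixed flg22/PTI list, planned as an alternative, is given first. Correlations between experiments used 100000 permutations. Scores and permutation tests ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

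Named genes were, per main comparison, called genes among the 10 largest rises and 10 largest falls with a mean log2 CPM of at least 1 and the same sign in every experiment, up to 4 called members of each list, and 8 fixed genes such as FRK1, FLS2 and MYB51 wherever measured. For strains they were the 3 largest rises and falls of the 8 strains with most calls, and genes called for flg22 in most strains. Each table of named genes allows more than are printed.

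Alternatives were RLE size factors, no filter on low counts, no experiment term, a block of experiment and replicate number, each experiment left out, libraries summed per group and experiment, pseudocount 0.25 in place of 1, and each of 11 libraries left out for HK-SynCom35. Leaving out libraries below a planned minimum of total counts would have removed none. Counts thinned to 1656231 per library, the doubted e3 libraries left out, the 2 HK-SynCom35 libraries left out, and a wider gene set for the response were added after seeing the data. Labels were checked by correlating each library with the mean profile of each group in the other experiments, over 2000 variable genes with a mean log2 CPM of at least 2. Other splits of the libraries within experiments were drawn with a fixed seed, 100 for flg22 against mock, 60 for the comparisons with No bacteria and between communities, and 25 for those over strains, the latter on 3000, 300 or 100 genes. The methods were tested on simulated data with known changes. No sample was left out of the values given first.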

Results

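The series measured RNA in whole seedlings of Arabidopsis thaliana (wild type Col-0) grown with or without 1 µM flg22, a peptide from bacterial flagellin that the plant receptor FLS2 binds, and with or without bacteria. The labels give 38 bacterial conditions, each without the peptide (mock) and with it, which makes 76 groups. The conditions are No bacteria, 34 single strains named by MF and CL codes, the mixed community SynCom35, its counterpart HK-SynCom35, and e.coli. What HK stands for is not stated in the labels. Plants were harvested 12 days after transfer, in 3 independent experiments called e1, e2 and e3 here. Of the 76 groups 65 held 9 libraries and 11 held fewer, and HK-SynCom35 was absent from e1. Total counts per library ran from 1656231 to 12775440, with a median of 3613582 in e1, 3366716 in e2 and 3488831 in e3. The 6 last-numbered conditions (CL21, CL69, e.coli, No bacteria, SynCom35 and HK-SynCom35) were sequenced deeper than the other 32 in e1 (median 6342445 against 3518940.5) and e2 (4385461 against 3299105), and near them in e3 (3608493 against 3480434), so most strains differ in depth and number range from the No bacteria control.

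A measured fact about e3 bears on the strain results. In e1, e2 and the first part of e3, libraries on average resembled the other experiments' libraries of their own labelled group, with mean correlations of 0.291, 0.330 and 0.350 across genes. Some did not, such as the MF136 mock libraries of e3, at -0.288, -0.358 and -0.427. For 94 e3 libraries in a run from MF181 mock replicate 3 to CL18 flg22 replicate 3, the mean correlation was 0.024 with the labelled group and 0.354 with the group 4 library numbers further on. These 94 libraries cover 15 strains in full and MF181 in part, and they are called the doubted e3 libraries here. In e3 7 pairs of libraries 4 numbers apart, all under different group labels, had counts more alike than any pair of 1 group (chi-square per gene 1.21 to 1.40, against 1.41 or more), so whether each is a separate library is open. Every strain direction is drawn from libraries as labelled, and counts without the doubted e3 libraries are given where stated. As these libraries were picked for their poor likeness to e1 and e2, more calls or closer experiments without them are partly built in.

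**Figure D1:**
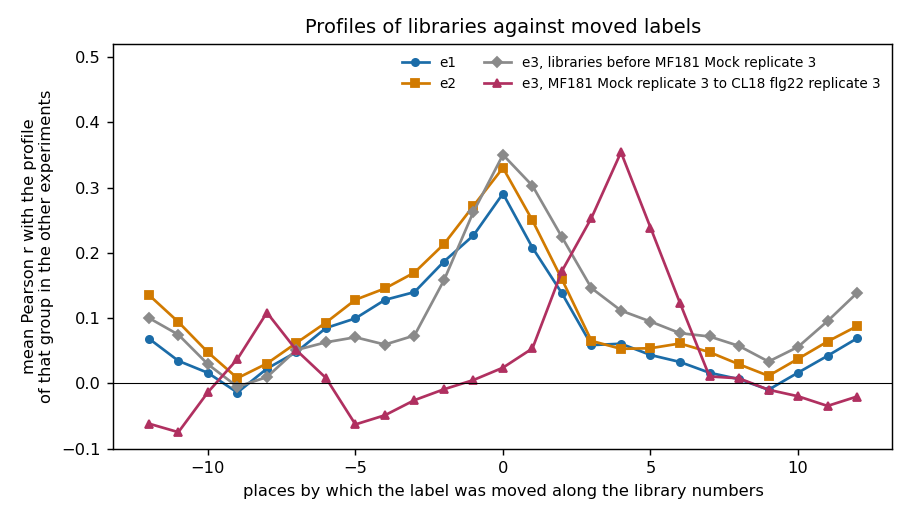
Mean Pearson correlation (y axis, across genes) between each library's profile and the profile of a labelled group in the other experiments, against how many library numbers the label was moved (x axis). The 94 doubted e3 libraries reach 0.354 at 4 numbers on and 0.024 at their own label, while libraries of e1, e2 and the first part of e3 are highest at their own label.

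The first comparison asked what flg22 did to seedlings grown without bacteria (9 flg22 and 8 mock libraries). FRK1 (AT2G19190), a receptor-like kinase gene known as a marker of flg22 perception and located on chromosome 2 at 8326049 to 8329944 of TAIR10.1, rose from 1.00 ± 0.586 to 19.3 ± 8.76 CPM (normalised counts, mean ± SD), a log2 fold change of 4.47 ± 0.24 (SE, adjusted p = 3.6e-13). AT2G43620, a chitinase family gene, rose by 5.68 ± 0.12 from 1.26 ± 0.398 to 66 ± 7.17 CPM. BARS1 (AT4G15370), which makes the triterpene baruol, rose by 6.20 ± 0.51 and XTH26 (AT4G28850), a cell wall enzyme of the xyloglucan endotransglucosylase family, by 4.21 ± 0.34. AT4G12490, a lipid transfer protein family gene, rose by 3.98 ± 0.57. Among the genes that fell were TIP2;3 (AT5G47450), a tonoplast aquaporin (-2.55 ± 0.36), and AGP30 (AT2G33790), an arabinogalactan protein of roots (-2.54 ± 0.26). In the edgeR test 3.27% of 17378 genes passed, 2.04% higher and 1.23% lower, and 13.9% had an unadjusted p under 0.05. DESeq2 called 3.34% of 21872 genes. Each called gene given with a log2 fold change, here and in the later comparisons up to the strains' own responses, moved in the same direction in every experiment that held both groups.

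**Figure D2:**
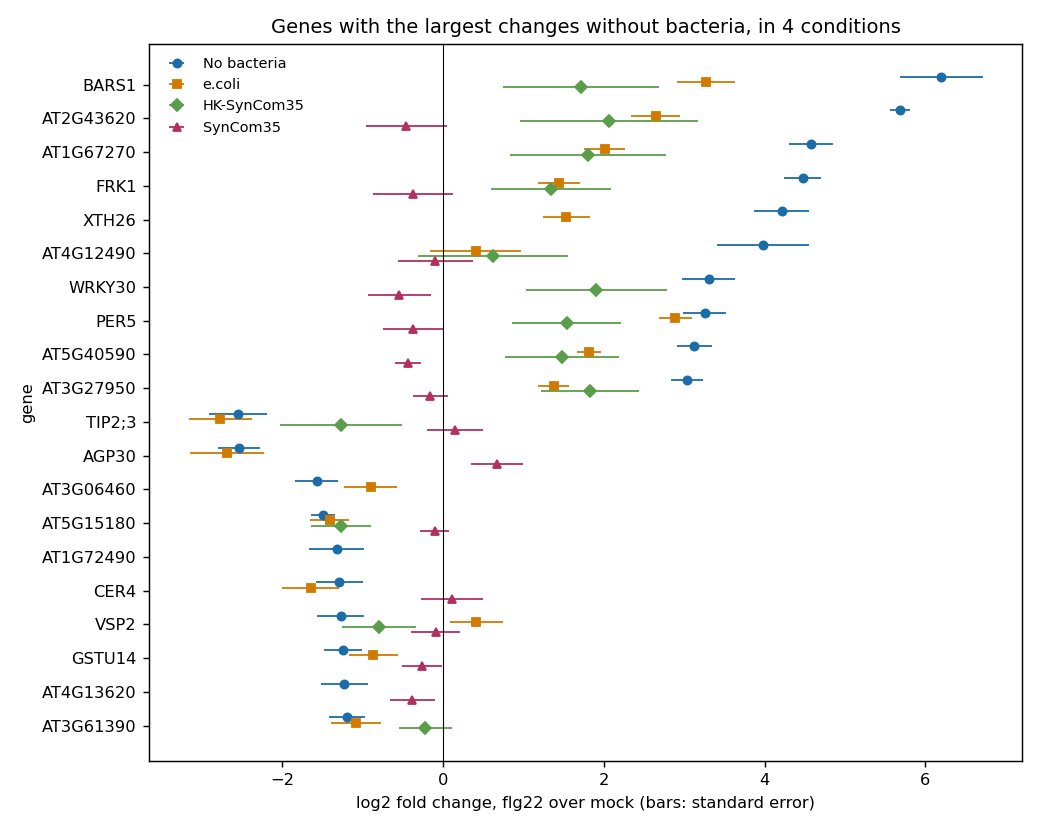
Log2 fold change of flg22 over mock (x axis, with SE as bars) for the 10 genes that rose most and the 10 that fell most without bacteria (y axis), in No bacteria, e.coli, HK-SynCom35 and SynCom35, where a gene under the count filter in a condition has no point. FRK1 lies at 4.47 ± 0.24 without bacteria, 1.45 ± 0.26 with e.coli, 1.34 ± 0.74 with HK-SynCom35 and -0.37 ± 0.50 with SynCom35.

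Of the fixed lists, the flg22/PTI markers, genes of pattern-triggered immunity, gave the smallest p in this comparison. Of 19 measured members 10 rose, 0 fell and 9 did not pass, or 12 risen when adjusted over the list alone (camera adjusted p = 1.2e-20, or adjusted p = 0.0022 with an estimated correlation). Beside FRK1 these were the transcription factor gene WRKY30 (AT5G24110, 3.3 ± 0.33), the peroxidase genes PER5 (AT1G14550, 3.25 ± 0.26) and PER4 (AT1G14540, 1.32 ± 0.15), and MYB51 (AT1G18570, 0.71 ± 0.10), a regulator of indole glucosinolate synthesis. Root hair genes rose as a list too, with 5 of 9 members higher and 8 adjusted over the list alone (adjusted p = 1.3e-11, or adjusted p = 0.0082 with an estimated correlation). Examples were the cell wall genes PRP3 (AT3G62680, 1.67 ± 0.17), LRX1 (AT1G12040, 1.07 ± 0.18) and EXPA7 (AT1G12560, 0.92 ± 0.13). The abscisic acid and water stress list fell, with 2 of 11 members lower, among them KIN1 (AT5G15960, -0.83 ± 0.15), and 6 adjusted over the list alone (adjusted p = 6.7e-05, or adjusted p = 0.0082 with an estimated correlation). In the anthocyanin and flavonoid list 3 of 8 members fell, including the flavanone hydroxylase gene F3H (AT3G51240, -0.46 ± 0.08), and 5 adjusted over the list alone (adjusted p = 6.9e-05, or adjusted p = 0.028 with an estimated correlation).

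The other called lists held with the preset correlation only. Jasmonate genes were lower in 2 of 15 members, 4 adjusted over the list alone, with VSP2 (AT5G24770) at -1.28 ± 0.29 and CORI3 (AT4G23600) at -0.96 ± 0.18 (list adjusted p = 5.5e-07, or adjusted p = 0.16 with an estimated correlation). Endodermis and suberin genes fell in 4 of 14 members, 7 adjusted over the list alone, among them the suberin genes FAR5 (AT3G44550, -0.64 ± 0.12) and GPAT5 (AT3G11430, -0.52 ± 0.12) (list adjusted p = 5.0e-05, or adjusted p = 0.12 with an estimated correlation). Of the camalexin list 2 of 10 members rose, both with all genes and adjusted over the list alone, one being GSTF6 (AT1G02930, 1.90 ± 0.22), a glutathione transferase (list adjusted p = 0.0021, or adjusted p = 0.22 with an estimated correlation). Of 17 indole glucosinolate genes 6 rose and 1 fell, or 7 and 1 adjusted over the list alone, with TSA1 (AT3G54640) at 0.43 ± 0.09 and IGMT2 (AT1G21120) at 0.75 ± 0.16 (list adjusted p = 0.0058, or adjusted p = 0.25 with an estimated correlation). In the phosphate starvation list 2 of 9 members rose, including the phosphate transporter gene PHT1;4 (AT2G38940, 1.03 ± 0.12) (list adjusted p = 0.0496, or adjusted p = 0.16 with an estimated correlation). The auxin list had 1 riser and 1 faller of 8 members (adjusted p = 0.030, or adjusted p = 0.21 with an estimated correlation), and no member of the aliphatic glucosinolate list passed (list adjusted p = 0.034, or adjusted p = 0.50 with an estimated correlation). No member passed in the lists of immune receptors (12 measured), salicylic acid (13), ethylene and defensins (5), photosynthesis (20), cell cycle (12), iron deficiency (17), nitrate assimilation (8), heat shock (2) or circadian clock (8), with list adjusted p from 0.20 to 0.91. In the ethylene and defensins list the median was -0.03 and the mean 0.06, so the signs differed. FLS2 (AT5G46330) itself was at 0.31 ± 0.20 (adjusted p = 0.55) and the light-harvesting gene LHCB1.1 (AT1G29920) at 0.10 ± 0.11 (adjusted p = 0.76).

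With SynCom35 (8 flg22 and 9 mock libraries) no gene passed the same test. FRK1 was at 18.5 ± 11.9 against 23.7 ± 22.5 CPM for flg22 against mock, a log2 fold change of -0.37 ± 0.50 (adjusted p = 1.0), negative in e1 and e2 and positive in e3, and MYB51 was at -0.14 ± 0.22. None of the 19 measured flg22/PTI markers passed, also adjusted over the list alone, and their median was -0.23 (camera adjusted p = 0.14). No list passed, the smallest adjusted p being 0.057, and the median and mean differed in sign for the endodermis and suberin list (0.03 and -0.01), while the auxin list had a negative median and mean and a test pointing upward. The count was 0 of 16987 genes in edgeR and 0 of 22998 in DESeq2, with 3.92% and 2.93% at an unadjusted p under 0.05. SynCom35 stood apart in e3, where mock replicates 1 and 2 correlated at -0.196 and -0.172 with the profile of their group in e1 and e2 and the flg22 response at -0.328 with that of e1 and e2, the lowest of 22 conditions outside the doubted libraries. The 9 mock libraries varied widely in FRK1, and without experiment e1 or e3 6 lists passed.

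With e.coli (9 flg22 and 9 mock libraries) FRK1 rose by 1.45 ± 0.26 (adjusted p = 0.0029), from 6.59 ± 5.83 to 16.2 ± 8.16 CPM. BARS1 rose by 3.27 ± 0.36, PER5 by 2.89 ± 0.21, AT2G43620 by 2.64 ± 0.30 and PER62 (AT5G39580), another peroxidase gene, by 2.47 ± 0.21. The strongest falls included ALD1 (AT2G13810, -3.12 ± 0.23) and FMO1 (AT1G19250, -2.18 ± 0.30), which make the systemic resistance signal N-hydroxypipecolic acid, along with TIP2;3 (-2.77 ± 0.39) and AGP30 (-2.69 ± 0.46). ALD1 and FMO1 fell from e.coli mock levels that were higher than without bacteria, as given below. In all 3.6% of 17367 genes passed, 1.08% higher and 2.52% lower, and DESeq2 called 4.37% of 20564. Of the genes called without bacteria that were tested here, 29% were called in the same direction with e.coli and none in the opposite one, where independent calls would coincide, in either direction, for 3.57%.

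By list, 4 of 18 flg22/PTI markers rose with e.coli, MYB51 by 0.65 ± 0.12, and adjusted over the list alone 4 rose and 2 fell (adjusted p = 0.015, or adjusted p = 0.44 with an estimated correlation). Salicylic acid genes fell in 3 of 16 members, ALD1, FMO1 and the salicylic acid synthesis gene PBS3 (AT5G13320, -1.21 ± 0.20), and 4 adjusted over the list alone (adjusted p = 7.0e-06, or adjusted p = 0.053 with an estimated correlation). Endodermis and suberin genes fell in 6 of 14, including CYP86A1 (AT5G58860, -0.63 ± 0.15), and 10 adjusted over the list alone (adjusted p = 5.0e-07, or adjusted p = 0.12 with an estimated correlation). Iron deficiency genes fell in 5 of 17 members, 7 adjusted over the list alone, among them the regulator FIT (AT2G28160, -1.38 ± 0.13) and the iron transporter gene IRT1 (AT4G19690, -1.45 ± 0.24) (list adjusted p = 7.4e-07, or adjusted p = 0.23 with an estimated correlation). Anthocyanin genes fell in 4 of 7, 6 adjusted over the list alone, with F3H at -0.64 ± 0.09 and chalcone synthase gene CHS (AT5G13930) at -0.56 ± 0.14 (list adjusted p = 6.4e-07, or adjusted p = 0.053 with an estimated correlation). Nitrate assimilation genes fell in 2 of 8, 4 adjusted over the list alone, among them the nitrate reductase gene NIA1 (AT1G77760, -0.62 ± 0.12) (list adjusted p = 1.9e-05, or adjusted p = 0.11 with an estimated correlation). The jasmonate (adjusted p = 0.0050, or adjusted p = 0.37 with an estimated correlation), aliphatic glucosinolate (adjusted p = 0.0094, or adjusted p = 0.56 with an estimated correlation) and heat shock (adjusted p = 0.0065, or adjusted p = 0.12 with an estimated correlation) lists passed downward with 0, 0 and 1 called member. The remaining lists did not pass. Without experiment e2 the share of genes called was 0.724%, and with no experiment term it was 1.16%.

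With HK-SynCom35 (5 flg22 and 6 mock libraries, e2 and e3 only) 9 genes passed, 8 higher and 1 lower. They included AT2G41810 (1.90 ± 0.30), the root hair gene LRX1 (1.29 ± 0.18), the zinc transporter gene ZIP3 (AT2G32270, 1.08 ± 0.21), the transcription factor gene WRKY18 (AT4G31800, 1.02 ± 0.20) and, downward, the receptor-like kinase gene AT5G59680 (-0.90 ± 0.17). FRK1 was at 1.34 ± 0.74 (adjusted p = 0.60). Of 18 flg22/PTI markers 0 passed, 1 adjusted over the list alone (list adjusted p = 3.8e-05, or adjusted p = 0.51 with an estimated correlation). None of 20 photosynthesis genes passed, although the list was lower with the preset correlation (adjusted p = 3.7e-08, or adjusted p = 0.51 with an estimated correlation). Root hair genes rose in 1 of 8 members, 4 adjusted over the list alone (list adjusted p = 3.0e-04, or adjusted p = 0.31 with an estimated correlation). The nitrate assimilation (adjusted p = 4.2e-04, or adjusted p = 0.29 with an estimated correlation), endodermis (adjusted p = 0.0032, or adjusted p = 0.51 with an estimated correlation), anthocyanin (adjusted p = 0.0058, or adjusted p = 0.51 with an estimated correlation) and iron deficiency (adjusted p = 0.017, or adjusted p = 0.54 with an estimated correlation) lists passed downward with no called member. For iron deficiency the median was 0.03 against a mean of -0.27, and the signs also differed in the salicylic acid, camalexin and phosphate lists, which did not pass. The 9 genes were 0.0549% of 16395, with 10.4% at an unadjusted p under 0.05, and DESeq2 called 0.188% of 16455.

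The HK-SynCom35 libraries labelled mock replicate 3 and flg22 replicate 3 of e3 each lay with the other treatment on genes called without bacteria. The mean score was 0.0664 for the first, where the other mock libraries ran from -1.39 to -1.11, and -1.08 for the second, where the other flg22 libraries ran from -0.121 to 0.320. Without both libraries 4.17% of 16411 genes passed. As both were picked for their place on genes that flg22 changes, part of that rise is built in. Without the mock library alone 2.76% passed, and without the flg22 library alone 0.282%. Leaving out any 1 of the other 9 HK-SynCom35 libraries left 0 to 3 genes.

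Whether a bacterial condition changed the flg22 response was tested as an interaction with No bacteria. With SynCom35 the response of BARS1 differed by -7.60 ± 1.03, that of AT2G43620 by -6.25 ± 0.71 and that of FRK1 by -4.79 ± 0.76 (log2, with SynCom35 minus without bacteria, adjusted p = 4.7e-04). The peroxidase genes PER5 (-3.66 ± 0.52) and PER4 (-1.55 ± 0.26), the camalexin gene GSTF6 (-2.22 ± 0.45) and the root hair gene EXPA7 (-1.21 ± 0.21) responded less. AGP30 (3.27 ± 0.51) and TIP2;3 (2.80 ± 0.52), which fell without bacteria, had a response that was higher by these amounts. In edgeR 0.712% of 17845 genes differed in response, 0.622% with a lower and 0.0897% with a higher one. With e.coli 55 of 18105 genes differed, 51 lower and 4 higher, among them AT2G43620 (-3.0 ± 0.48), FRK1 (-3.0 ± 0.47), AT3G04320 (-1.82 ± 0.26) and GSTF6 (-1.69 ± 0.30). With HK-SynCom35 0 of 17896 genes passed in edgeR, 4.32% having an unadjusted p under 0.05, and no other tool was run for interactions. Without experiment e1 no gene differed with e.coli, and without e2 4 did. A lower response can come from a higher level in mock as well as from a lower level with flg22. FRK1 and GSTF6 were higher in mock with SynCom35 and with e.coli, as given below. Among flg22-treated seedlings 6.51% of genes differed between SynCom35 and No bacteria, and 1.16% between e.coli and No bacteria.

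Among the 34 single strains a median of 1 gene responded to flg22, 16 strains had no called gene and 16 had 10 or more. The most were called with MF2 (1139 genes, 6.80%), MF125 (4.98%) and MF33 (3.18%), where No bacteria had 3.27%. This order is of libraries as labelled, and without the doubted e3 libraries MF360 had 5.29% (14 genes as labelled), and MF339 2.63% and MF302 2.28% (both 0 genes as labelled). Leaving out the doubted e3 libraries gave a median of 54.5 genes, with 8 strains at 0. The gene called in most strains was AT2G47550, a pectin methylesterase family gene, which rose in 9 strains, and the chitinase family gene AT2G43610, the expansin gene EXPA17 (AT4G01630), AT2G41810 and AT1G54890 were among the genes that rose in 7. The light stress gene ELIP1 (AT3G22840) and the cytochrome P450 gene CYP702A5 (AT4G15393) fell in 7 strains, and the oxophytodienoate reductase gene OPR1 (AT1G76680) and FIT fell in 6. None of these was called in the opposite direction in any strain. These counts of strains per gene are from the libraries as labelled and were not repeated without the doubted e3 libraries. The interaction against No bacteria passed for a median of 61.5 genes per strain, 68.5 without the doubted e3 libraries. Against No bacteria in mock, the median share of genes that differed was 3.85% per strain, and 6.36% without these libraries. Both medians were lower without e1, without e2, with no experiment term and with summed libraries, as given in the section on processing.

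Averaged over the 34 strains, the flg22 response was small and widespread. The largest rises were those of AT1G67270 (1.37 ± 0.11), BARS1 (1.24 ± 0.12), PER5 (1.15 ± 0.10), AT2G43620 (1.01 ± 0.11), PER62 (0.99 ± 0.09) and AT2G47550 (0.94 ± 0.07). The largest fall was that of SAG12 (AT5G45890, -2.64 ± 0.34), a senescence protease gene, whose mean log2(CPM + 1) changed by -0.16 in e1, -0.25 in e2 and -0.04 in e3. It was followed by genes of salicylic acid defence such as PR1 (AT2G14610, -1.01 ± 0.19), PR2 (AT3G57260, -0.74 ± 0.12) and ALD1 (-0.68 ± 0.09), and by the heat shock factor gene HSFA2 (AT2G26150, -0.73 ± 0.09). FRK1 was at 0.23 ± 0.10 (adjusted p = 0.064). In edgeR 27.7% of 19181 genes passed, 13.2% higher and 14.5% lower, but only 0.495% changed by more than 0.5 on the log2 scale and 9 genes by more than 1. Like the other fits given first, this fit had no term for an effect that varies between experiments. The SE and adjusted p of all these fits thus rest on the spread between libraries. They do not measure that between experiments. Of the genes called without bacteria 68% were called in the same direction in this average and 0.527% in the opposite one, where independent calls would coincide, in either direction, for 28.3%.

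In that average salicylic acid genes fell in 13 of 18 members, 14 adjusted over the list alone (adjusted p = 3.5e-09, or adjusted p = 0.094 with an estimated correlation), and iron deficiency genes in 12 of 21, 14 adjusted over the list alone, with FIT at -0.37 ± 0.05 and IRT1 at -0.38 ± 0.06 (adjusted p = 1.3e-07, or adjusted p = 0.19 with an estimated correlation). Endodermis genes fell in 11 of 14, with FAR5 at -0.23 ± 0.03 (adjusted p = 1.8e-06, or adjusted p = 0.11 with an estimated correlation), and jasmonate genes in 10 of 19, 12 adjusted over the list alone (adjusted p = 1.3e-05, or adjusted p = 0.24 with an estimated correlation). Of 21 flg22/PTI markers 8 rose and 3 fell, 9 and 3 adjusted over the list alone (adjusted p = 5.8e-04, or adjusted p = 0.31 with an estimated correlation). Root hair genes rose in 4 of 9, PRP3 by 0.31 ± 0.05 (adjusted p = 0.0015, or adjusted p = 0.31 with an estimated correlation). The heat shock (3 of 4), aliphatic glucosinolate (9 of 12), anthocyanin (7 of 14) and nitrate (5 of 8) lists fell with adjusted p from 2.9e-04 to 0.0086, and adjusted p from 0.070 to 0.31 with an estimated correlation. Immune receptors (7 of 14 lower, 2 higher) and photosynthesis (4 of 20 higher, 1 lower) passed at adjusted p = 0.020 and 0.041, against adjusted p = 0.31 and 0.67 with an estimated correlation. Median, mean and test differed in sign in the camalexin and phosphate lists, which did not pass. The share of genes called was 6.49% without experiment e2 and 33.9% without the doubted e3 libraries.

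The size of the flg22 response was compared between each of 37 bacterial conditions and No bacteria as the mean change of the flg22/PTI markers, in log2(CPM + 1). Seedlings without bacteria responded by 0.797 ± 0.0732 (SD over 3 experiments). The response was 0.784 ± 0.0421 with strain MF2, 0.462 ± 0.424 with HK-SynCom35 (0.762 in e2, and 0.162 in e3 with the 2 libraries that lay with the other treatment), 0.291 ± 0.151 with e.coli, -0.0117 ± 0.321 with MF109 and -0.153 ± 0.243 with SynCom35. All 37 conditions had a lower mean than No bacteria, and 32 differed in a two-sided exact permutation test within experiments and treatments (adjusted p = 1.0e-05 for MF109, 6.1e-04 for SynCom35 and 0.0047 for e.coli). MF2 (adjusted p = 0.93), HK-SynCom35 (0.17), MF33 (0.16), MF302 (0.16) and MF362 (0.070) did not. In mock the same list was higher than without bacteria in all 37 conditions by sign. The No bacteria mock libraries enter both comparisons, so a higher mock level can give a smaller response. List levels in flg22-treated seedlings were not compared. A simulated chance deviation of the shared control gave a 95th percentile of 19.1 conditions, against 32 at an unadjusted p under 0.05. The set planned for the response size, genes called in a set share of the other conditions, held only 1 or 2 genes per condition, and gave 31 smaller responses. In 28 conditions it includes AT2G41810, which No bacteria calls and those conditions do not, so a smaller response is partly built into that count. With genes called in 3 or more other conditions, a wider set chosen after seeing the data, 5 conditions differed, and without the doubted e3 libraries the fixed list gave 28.

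**Figure D3:**
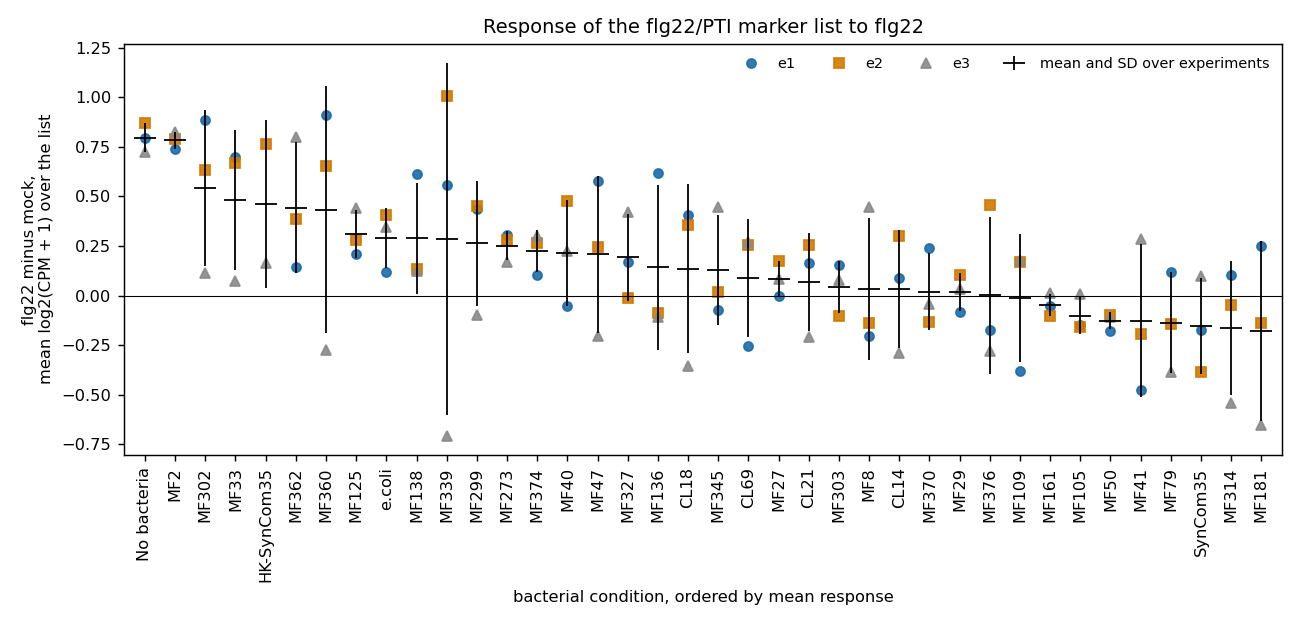
Mean flg22 response of the flg22/PTI markers in log2(CPM + 1) (y axis) for each of the 38 conditions (x axis), with one point per experiment and the mean and SD over experiments. No bacteria lies at 0.797 ± 0.0732 and SynCom35 at -0.153 ± 0.243.

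How far the order of the conditions repeated was asked with the planned gene set, in 3 correlations between experiments. This set held 1 gene in the 10 conditions that call AT2G41810 and 2 in the other 28. As the set thus follows the response, part of the likeness between experiments is built in. With the fixed flg22/PTI list, r was 0.618 between e1 and e2 (permutation p = 6.0e-05, adjusted 1.8e-04), -0.0674 between e1 and e3 (p = 0.69) and 0.124 between e2 and e3 (p = 0.46). With the planned set, Pearson's r between e1 and e2 was 0.746 over 37 conditions (permutation test, two-sided, p = 1.0e-05, the smallest that the permutations can give, adjusted 3.0e-05), Spearman's rho 0.651 (p = 2.0e-05), and r without MF2 and MF79, the farthest conditions, 0.722. Between e1 and e3 r was 0.252 (p = 0.13, adjusted 0.18), rho 0.209 (p = 0.21) and r without the same conditions 0.174. Between e2 and e3 r was 0.223 over 38 conditions (p = 0.18, adjusted 0.18), rho 0.130 (p = 0.43) and r without CL21 and MF2 0.0982. Without the doubted e3 libraries r was 0.589 between e1 and e3 (21 conditions, permutation p = 0.0056) and 0.679 between e2 and e3 (22 conditions, permutation p = 6.5e-04). The doubted libraries were picked for their poor likeness to e1 and e2, so part of this rise is built in. The permutation p takes no account of that choice. With the fixed list and without the doubted e3 libraries r was 0.172 (permutation p = 0.46) and 0.522 (permutation p = 0.012), or -0.339 and 0.206 without No bacteria and MF2.

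What bacteria did without the peptide was asked against No bacteria mock (8 libraries). With SynCom35 (9 libraries) FRK1 rose from 1.00 ± 0.586 to 23.7 ± 22.5 CPM, by 4.63 ± 0.61 (adjusted p = 5.8e-06), and AT2G43620 by 4.38 ± 0.59. The nitrate transporter gene NRT2.5 (AT1G12940) rose by 5.55 ± 0.80 and the defensin gene PDF1.2 (AT5G44420) by 5.20 ± 1.17. CYP82C4 (AT4G31940), a cytochrome P450 gene of iron-deficiency coumarin synthesis, fell most (-5.69 ± 0.75, from 16.3 ± 12.0 to 0.392 ± 0.525 CPM), followed by the detoxification genes CYP81D11 (AT3G28740, -3.88 ± 0.24) and GSTU24 (AT1G17170, -2.80 ± 0.27). In edgeR 7.38% of 17845 genes passed, 4.33% higher and 3.05% lower. Of the genes that flg22 changed without bacteria 38.4% were called in the same direction here and 1.41% in the opposite one, where independent calls would coincide, in either direction, for 6.97%. Both comparisons use the No bacteria mock libraries, so their calls are not independent.

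Of 20 flg22/PTI markers 13 rose with SynCom35, 16 adjusted over the list alone, WRKY53 (AT4G23810) by 1.90 ± 0.27 (list adjusted p = 2.0e-16, or adjusted p = 0.0030 with an estimated correlation). Immune receptor genes rose in 4 of 14, 8 adjusted over the list alone, among them RLP23 (AT2G32680, 3.67 ± 0.60) and EFR (AT5G20480, 1.27 ± 0.27), while FLS2 was at 0.26 ± 0.23 (list adjusted p = 7.5e-06, or adjusted p = 0.041 with an estimated correlation). Salicylic acid genes rose in 10 of 15, 14 adjusted over the list alone, such as PR5 (AT1G75040, 2.0 ± 0.35) and PAD4 (AT3G52430, 0.67 ± 0.13) (adjusted p = 1.0e-10, or adjusted p = 0.024 with an estimated correlation). Camalexin genes rose in 5 of 10, 8 adjusted over the list alone, with GSTF6 at 2.39 ± 0.33 and the camalexin synthesis gene PAD3 (AT3G26830) at 2.23 ± 0.49 (adjusted p = 6.1e-08, or adjusted p = 0.014 with an estimated correlation). Indole glucosinolate genes rose in 8 of 17, 12 adjusted over the list alone, with ASA1 (AT5G05730) at 0.69 ± 0.13 and MYB51 at 0.85 ± 0.17 (adjusted p = 2.1e-08, or adjusted p = 0.0049 with an estimated correlation). Abscisic acid genes fell in 6 of 11, 9 adjusted over the list alone, with KIN1 at -2.26 ± 0.28, HB7 (AT2G46680) at -1.10 ± 0.14 and NCED3 (AT3G14440), an enzyme of abscisic acid synthesis, at -1.85 ± 0.31 (adjusted p = 4.4e-11, or adjusted p = 3.0e-04 with an estimated correlation). Endodermis genes fell in 5 of 14, 7 adjusted over the list alone, with CYP86A1 at -0.91 ± 0.15 and GPAT5 at -0.93 ± 0.17 (adjusted p = 2.4e-06, or adjusted p = 0.084 with an estimated correlation). The ethylene (adjusted p = 0.023, or adjusted p = 0.32 with an estimated correlation) and aliphatic glucosinolate (adjusted p = 0.017, or adjusted p = 0.57 with an estimated correlation) lists passed upward with 2 risen members each and 1 fallen ethylene member, and the photosynthesis (adjusted p = 0.031, or adjusted p = 0.64 with an estimated correlation) and anthocyanin (adjusted p = 0.031, or adjusted p = 0.43 with an estimated correlation) lists downward. Iron deficiency genes, which did not pass, had a median of 0.18 and a mean of -0.03. The share of genes called was 3.63% without experiment e1 and 3.6% with libraries summed per group and experiment.

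With e.coli (9 mock libraries) FRK1 rose by 2.77 ± 0.41 (adjusted p = 5.1e-05) and the camalexin gene CYP71A12 (AT2G30750) by 1.63 ± 0.35. Systemic resistance genes rose, FMO1 by 2.59 ± 0.36, ALD1 by 2.31 ± 0.26, PBS3 by 1.77 ± 0.24 and the transcription factor gene CBP60G (AT5G26920) by 1.21 ± 0.15, as 7 of 16 members of their list, or 11 adjusted over the list alone (adjusted p = 6.4e-13, or adjusted p = 0.0014 with an estimated correlation). Of the flg22/PTI markers 10 of 20 rose, 11 adjusted over the list alone (adjusted p = 3.4e-11, or adjusted p = 0.014 with an estimated correlation). Of the camalexin list 4 of 10 rose and 1 fell, 6 and 1 adjusted over the list alone, with GSTF6 at 1.97 ± 0.23 (adjusted p = 1.1e-07, or adjusted p = 0.046 with an estimated correlation). Iron deficiency genes rose in 3 of 19, 9 adjusted over the list alone, including the coumarin genes F6'H1 (AT3G13610, 1.41 ± 0.17) and S8H (AT3G12900, 1.52 ± 0.33) (adjusted p = 4.6e-09, or adjusted p = 0.057 with an estimated correlation). ALD1, FMO1, PBS3 and iron deficiency genes were given above as falling with flg22 from the same e.coli mock libraries. Their rise here and that fall are thus not independent. Indole glucosinolate genes rose in 4 of 17, IGMT2 by 1.42 ± 0.18 (adjusted p = 2.2e-05, or adjusted p = 0.057 with an estimated correlation). The auxin-conjugating enzyme gene GH3.2 (AT4G37390) rose by 1.81 ± 0.23, while the auxin list, like the anthocyanin and circadian clock lists, did not pass and differed in sign between median, mean and test. Abscisic acid genes fell in 2 of 11, with HAI1 (AT5G59220) at -0.86 ± 0.23 (adjusted p = 0.0017, or adjusted p = 0.13 with an estimated correlation), and the asparagine synthetase gene ASN1 (AT3G47340) fell (-1.33 ± 0.22). Immune receptors, ethylene, heat shock, nitrate and root hair lists passed upward and photosynthesis downward with the preset correlation, but with an estimated correlation their adjusted p was 0.057, 0.057, 0.052, 0.16, 0.47 and 0.75 in that order. In edgeR 4.81% of 18105 genes passed, 2.99% higher and 1.81% lower, and 1.46% with no experiment term.

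With HK-SynCom35 (6 mock libraries) no gene passed against No bacteria, 0 of 17896 in edgeR with 4.95% at an unadjusted p under 0.05, and no other tool was run. FRK1 was at 3.49 ± 0.70 (adjusted p = 0.21). Of the 6 libraries, e3 replicate 3 lay with the flg22 libraries, with a score of 0.0664 where the others ran from -1.39 to -1.11. The abscisic acid list fell, with 0 of 11 members called and 5 adjusted over the list alone (adjusted p = 2.9e-08, or adjusted p = 9.4e-04 with an estimated correlation). The flg22/PTI (adjusted p = 6.0e-04, or adjusted p = 0.37 with an estimated correlation) and iron deficiency (adjusted p = 9.7e-06, or adjusted p = 0.23 with an estimated correlation) lists passed upward, and the jasmonate (adjusted p = 2.2e-06, or adjusted p = 0.21 with an estimated correlation) and anthocyanin (adjusted p = 1.4e-04, or adjusted p = 0.056 with an estimated correlation) lists downward, none with a called member. Signs differed in the aliphatic glucosinolate and cell cycle lists, which did not pass. Without experiment e3 0.212% of genes passed and 11 lists.

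Mean list levels in mock libraries were then compared with No bacteria in each of the 37 conditions (two-sided exact permutation test, adjusted over lists and conditions). The salicylic acid list was higher in 25 conditions, the flg22/PTI list in 22, immune receptors in 21, ethylene and defensins in 16, root hair in 15, camalexin in 14 and iron deficiency in 13. Indole glucosinolate genes were higher in 14 and lower in 2. The abscisic acid list was lower in 30 conditions, anthocyanin lower in 10 and higher in 2, and endodermis and suberin lower in 7. Without the doubted e3 libraries the salicylic acid list was higher in 22, flg22/PTI in 19, immune receptors in 15, camalexin in 13, root hair and iron deficiency in 12 each, and ethylene and indole glucosinolate in 10 each. The abscisic acid list was then lower in 24, anthocyanin in 9 and endodermis in 8, with anthocyanin higher in 2 and indole glucosinolate lower in 1. In response to flg22 the flg22/PTI list was smaller than without bacteria in 25 conditions and the root hair list in 18, or 19 and 13 without these libraries. The same No bacteria mock libraries enter the mock and the response counts, which are thus not independent. A higher mock level can give a smaller response. All conditions share 1 control, and in a simulation of its chance deviation, chosen after the results were seen, the counts at an unadjusted p under 0.05 for higher iron deficiency (18, simulated 95th percentile 24.05), lower anthocyanin (12, 13.3) and lower endodermis and suberin genes (14, 17) lay within what chance gave. Without e1 or e3 the exact test of mock levels has so few assignments that a pair passes only if many pairs reach the smallest p. The mock counts that follow thus do not show dependence on an experiment. None of the mock differences passed without experiment e1, while 13.2% of the list and condition pairs passed without e2 and 11.6% without e3, against 30% with all.

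**Figure D4:**
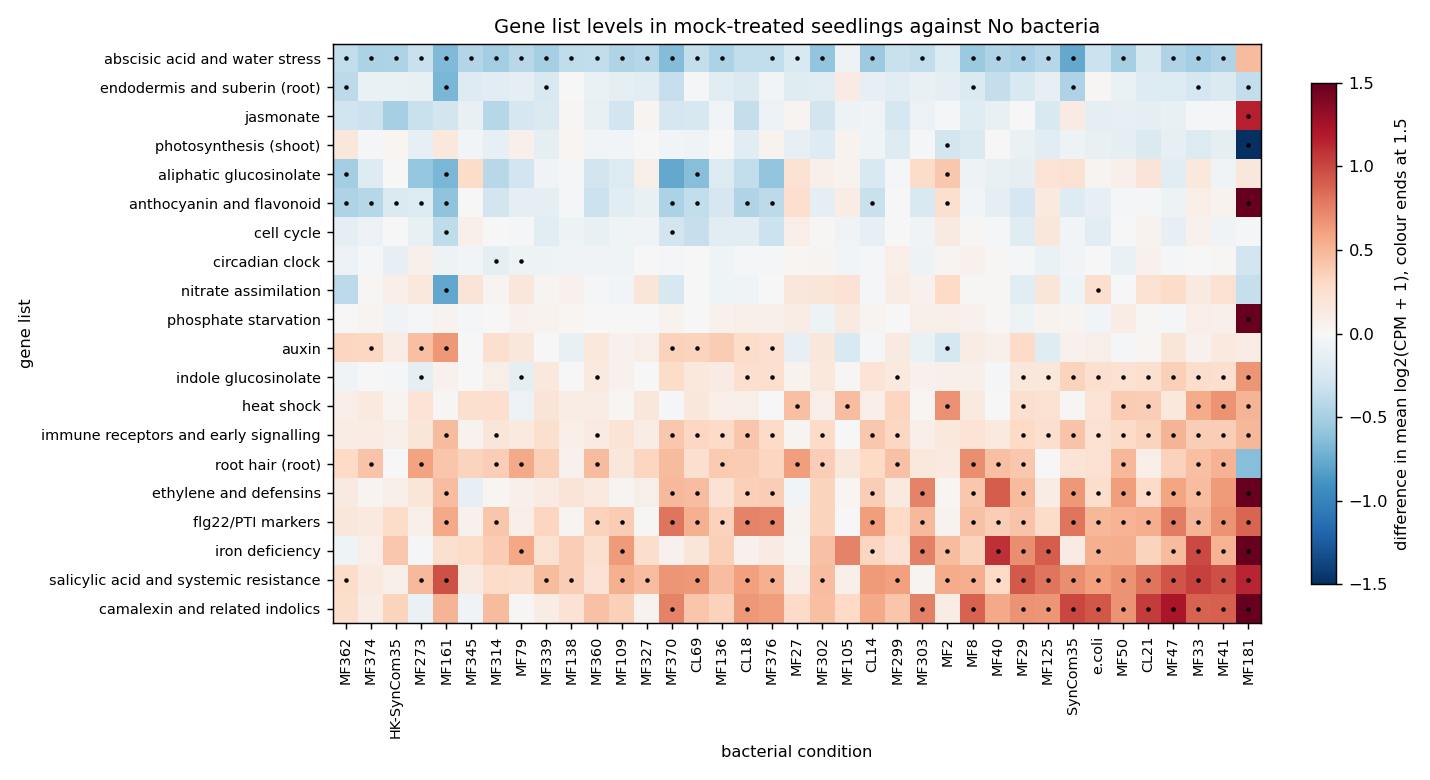
Difference of mean list level from No bacteria in mock libraries, in log2(CPM + 1) (colour), for each fixed list (y axis) in 37 conditions (x axis), with dots where the exact test passed. The abscisic acid list is lower in 30 conditions and the salicylic acid list higher in 25.

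SynCom35 was compared with HK-SynCom35 in e2 and e3 (6 and 6 mock libraries). CYP82C4 was lower with SynCom35, at 0.493 ± 0.601 against 31.8 ± 11.9 CPM (-6.09 ± 0.54, adjusted p = 2.5e-07). CYP81D11 (-3.58 ± 0.27), the nicotianamine synthase gene NAS2 (AT5G56080, -3.13 ± 0.37) and the glutathione transferase gene GSTU25 (AT1G17180, -2.52 ± 0.22) were lower too, and AT5G04730 was higher (3.02 ± 0.42). Indole glucosinolate genes were higher in 5 of 17 members, 8 adjusted over the list alone, UGT74B1 (AT1G24100) by 0.75 ± 0.13 (list adjusted p = 6.8e-06, or adjusted p = 0.089 with an estimated correlation). Camalexin genes were higher in 3 of 10, CYP79B2 (AT4G39950) by 1.11 ± 0.16 and PAD3 by 2.24 ± 0.47 (adjusted p = 1.1e-04, or adjusted p = 0.20 with an estimated correlation), and jasmonate genes in 2 of 15, 7 adjusted over the list alone, MYC2 (AT1G32640) by 0.76 ± 0.12 (adjusted p = 0.0011, or adjusted p = 0.25 with an estimated correlation). The flg22/PTI list had 2 of 18 members higher, 6 adjusted over the list alone, the salicylic acid list 1 of 15, EDS5 (AT4G39030, 0.92 ± 0.22), and the aliphatic glucosinolate list 3 of 12, each at adjusted p = 1.2e-04, or adjusted p = 0.25 with an estimated correlation. Abscisic acid genes were lower in 2 of 8 (adjusted p = 0.010, or adjusted p = 0.25 with an estimated correlation), and in the ethylene and defensins list, which did not pass, PR3 (AT3G12500) was lower (-1.18 ± 0.25). The root hair list passed upward and the endodermis and photosynthesis lists downward, at adjusted p from 0.037 to 0.049, and adjusted p from 0.56 to 0.73 with an estimated correlation. Signs differed in the cell cycle and iron deficiency lists, which did not pass. In edgeR 4.76% of 17093 genes passed, 1.99% higher and 2.77% lower, and 0.915% with libraries summed per group and experiment. The HK-SynCom35 mock libraries include e3 replicate 3, which lay with the flg22 libraries. Without both HK-SynCom35 libraries described above 4.84% of 17223 genes passed, and the lists were not tested again without them.

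In flg22-treated seedlings (5 and 5 libraries) 2.21% of genes differed between SynCom35 and HK-SynCom35, 1.08% higher and 1.13% lower. CYP82C4 (-4.01 ± 0.61), NAS2 (-3.58 ± 0.51), CYP81D11 (-3.29 ± 0.31), GSTU25 (-3.15 ± 0.25) and the polygalacturonase inhibitor gene PGIP1 (AT5G06860, -2.66 ± 0.40) were lower with SynCom35. AT5G04730 (2.63 ± 0.52), the auxin-induced root gene AIR1 (AT4G12550, 2.33 ± 0.49) and MYC2 (0.64 ± 0.13) were higher. Of the genes called in mock 26.7% were called in the same direction with flg22, where independent calls would coincide, in either direction, for 2.21%. No gene's flg22 response differed between the communities, 0 of 17093 in edgeR with 3.73% at an unadjusted p under 0.05, and 0.343% of 17223 without both HK-SynCom35 libraries described above.

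Each strain was finally compared with the mean of the other strains in mock. MF181 stood far apart, with 66.3% of genes called, and 68.4% without the doubted e3 libraries. AT1G12030 rose by 8.62 ± 0.14, the defensin gene PDF1.2c (AT5G44430) by 8.12 ± 0.25 and the jasmonate-induced acetyltransferase gene NATA1 (AT2G39030) by 7.38 ± 0.21, while AT5G62420 (-4.09 ± 0.53) and BARS1 (-3.74 ± 0.95) fell. All 20 measured photosynthesis genes were lower with MF181, with a median of -1.40. All 12 anthocyanin genes were higher (median 3.64), as were 12 of 13 phosphate starvation genes, 16 of 18 jasmonate genes, 10 of 11 ethylene and defensin genes and 9 of 10 camalexin genes. Of the flg22/PTI markers 12 of 20 were higher and 7 lower. These lists were counted by gene calls alone, with no list test for single strains.

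With MF161 (21.0% of genes, and 24.7% without the doubted e3 libraries) BARS1 rose by 2.94 ± 0.32 and the polygalacturonase gene PGAZAT (AT2G41850) by 2.07 ± 0.30, the nitrate transporter gene NRT2.1 (AT1G08090) fell (-2.66 ± 0.29), 16 of 20 photosynthesis genes and 11 of 18 salicylic acid genes were higher, and 10 of 14 endodermis and 7 of 8 nitrate genes were lower. With MF2 (18.1% and 17.7%) HSFA2 rose by 2.02 ± 0.28, CYP82C2 (AT4G31970, -2.65 ± 0.63) and XTH26 (-2.43 ± 0.66) fell, 9 of 12 aliphatic glucosinolate genes were higher and 7 of 9 auxin genes lower. With MF370 (12.4% and 16.8%) NRT2.5 rose by 2.31 ± 0.36 and the amino acid enzyme gene BCAT-2 (AT1G10070) by 2.18 ± 0.27, the iron-signalling peptide gene IMA3 (AT2G30766) fell (-1.34 ± 0.40), and 11 of 20 flg22/PTI markers were higher. With MF376 (11.6% and 15.4%) SEN1 (AT4G35770) rose by 1.42 ± 0.29, NAS2 (-1.81 ± 0.41) and IMA1 (AT1G47400, -1.65 ± 0.56), another such peptide gene, fell, and 7 of 20 flg22/PTI markers were higher. With MF27 (10.9% and 12.2%) AT5G47980 rose by 1.85 ± 0.29, NRT2.5 (-4.22 ± 1.02) and CYP82C4 (-3.91 ± 0.92) fell, and 9 of 18 salicylic acid genes were lower. With CL69 (5.71% and 11.1%) TIP2;3 rose by 1.51 ± 0.23 and AGP30 by 1.31 ± 0.28, and IMA1 fell (-1.54 ± 0.44). With CL18 (4.09% and 5.39%) NRT2.5 rose by 1.64 ± 0.36, IMA3 fell (-1.18 ± 0.35), and AT2G43620 rose by 1.69 ± 0.34, a call lost without the doubted e3 libraries (1.07 ± 0.47, adjusted p = 0.17). IMA1 with MF370 (-1.80 ± 0.62) was lost likewise (-1.43 ± 0.62, adjusted p = 0.097). Over all strains the median share of genes that differed from the mean of the others was 0.788%, and 1.31% without the doubted e3 libraries. It was 0.0963% without experiment e2 and 0.474% with no experiment term.

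The flg22 response of each strain was compared with the mean response of the others. For MF2 74 genes differed, 51 of them with a higher response. XTH26 (3.37 ± 0.69) and BARS1 (3.06 ± 0.76) responded more and ALD1 (-2.54 ± 0.67) less, 3 genes named after their values were seen. For MF181 1360 genes (7.09% of 19181) differed as labelled. These were the strains with 10 or more genes, and without the doubted e3 libraries there were 6, with 3.12% of 19309 genes for MF181, 1.26% for MF339, 89 genes for MF360, 70 for MF2, 12 for MF40 and 10 for MF299. Chance cannot be excluded for the calls over all strains as labelled, since 12 of 25 splits of the libraries reached the real share.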

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

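The tests of the e3 labels by profile correlation and by MF181 score, those of the HK-SynCom35 libraries, the simulation of a shared control and the use of counts thinned to 1 total were chosen after the results were seen.

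The flg22 response differed from that without bacteria in 0.712% of genes with SynCom35, in 0.304% with e.coli, in a median of 61.5 genes per strain, and on the flg22/PTI list in 32 of 37 conditions, each by a test of the difference itself. With SynCom35 1 of 60 splits of the libraries, the real one, reached that share, and the highest other gave 0.0448%. That is the smallest share that 60 splits can give, so other splits seldom reach the real value. As the splits moved single libraries within experiments, they do not test variation between experiments. With e.coli 2 of 60 splits reached the real share, which is under a share of 0.05. As another split called 0.724% of genes, more than the real 0.304%, chance is not excluded there. For the strains, 1 of 25 splits reached the real median, 0.35% of 3000 genes against a highest other of 0. This is the smallest share that 25 splits can give, under a share of 0.05 but too coarse to exclude chance. With HK-SynCom35 the real value was 0 in edgeR, with 4.32% of genes at an unadjusted p under 0.05 and a highest other of 0.112%. For the difference in response between SynCom35 and HK-SynCom35 it was 0 in edgeR too, with 3.73% at an unadjusted p under 0.05 and a highest other of 0.222%. A real value of 0 is reached by any split, here 60 of 60, so for these 2 the splits decide nothing.

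In e3 the 94 doubted libraries stood apart from e1 and e2 under their labels. Their mean correlation with the group 4 library numbers on was 0.330 above that with their own, and 78 of 94 lay closer to that group against 27 of the other e3 libraries. Over 15 strains the e3 response to flg22 correlated with that in e1 and e2 at a median of 0.282 with labels moved 4 places and 0.00526 as labelled, higher in 12 strains, where 22 conditions outside gave 0.25. Against an exchange of mock and flg22 stands a correlation of 0.0877 with the same strain under the other treatment, and against plants that responded differently in e3 a highest MF181 score of -0.141 in the doubted libraries labelled MF181, with 2.83 or more in e3 before them and 2.76 to 3.03 in e1 and e2. A shift of the labels by 4 places may be the cause, as a hypothesis found and tested on the same data, but the 7 most alike of 73609 pairs of libraries, 4 numbers apart in e3 under different labels, leave open that a library may be listed under 2 labels, which was not tested and which would make the numbers of libraries too high.

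Among the mock libraries of HK-SynCom35, e3 replicate 3 was far above the others on the flg22/PTI list, at 3.92, and among the flg22 libraries e3 replicate 3 far below, at 3.0. An exchange of these 2 libraries may be the cause, but on genes called without bacteria the flg22 library's score of -1.08 lay just above the other mock libraries, -1.39 to -1.11, which leaves it open. Against library size stands, for the mock library, a total of 4361377 that lay among the others (2463191 to 4729002), but for the flg22 library, whose total of 2201886 lay below them, size and exchange cannot be told apart. No biological explanation was tested, as the labels give none for single libraries. Without both libraries 4.17% of genes passed for flg22, as against 0.0549%. As they were picked for their place on genes that flg22 changes, this rise is partly built in and is no independent evidence of a response.

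The abscisic acid list was lower with bacteria in mock, in 36 of 37 conditions by sign, MF181 being the exception. A pool of the last-numbered libraries would set No bacteria apart from the rest, but CL21, CL69 and e.coli of the same number range had a median difference of -0.322, against -0.444 over all conditions. Library size would make the differences go, but at 1 total 36 of 37 conditions stayed negative, with a median of -0.406. As the 37 comparisons share 1 control, a chance deviation of that control was simulated, and where 33 conditions were lower at p under 0.05 the simulated 95th percentile was 7.15, with 0 of 100 simulations as large. A response of the plants to bacteria may be the cause, a hypothesis found and tested on the same data, while a peculiarity of the No bacteria seedlings in all 3 experiments was not tested.

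The mock library of SynCom35 labelled e1 replicate 2 had a total count of 9698041, where the other 8 ran from 2280137 to 5935737. A library lay this far from its group in 12 of 76 groups (15.8%) for total count and in 8 of 76 (10.5%) for the flg22/PTI list, where chance gives about 1 in 20 groups.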

How the results depend on the processing

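The counts thinned to 1 total, the settings without the doubted e3 libraries or without both HK-SynCom35 libraries, and the wider gene set were chosen after the results were seen. The doubted e3 libraries were picked for poor likeness to e1 and e2, and the HK-SynCom35 libraries for their place on flg22 genes. Values that rise without them are thus partly built in. Counts are by edgeR unless DESeq2 is named. Genes named in the text were recomputed in 1342 alternatives, of which 1185 (88.3%) kept direction and side of the threshold. A change of sign where neither value passed was counted as kept. Most others lost the call in the same direction, 6 passed where the value first given had not, and 0 reversed. Many of these genes were named only if their sign was the same in every experiment, so few reversals could arise. Of the alternatives to 34 counts and correlations 53.6% stayed within 1.5 times the first value or on its side of the threshold, among them all 19 results under RLE size factors. With SynCom35 flg22 gave 0 called genes in all 10 alternatives, and with HK-SynCom35 so did the interaction. Dropping an experiment or summing leaves fewer libraries, thinning leaves fewer counts, and where a value rose or any other setting moved it the cause was not tested. Planned but not run were RLE, each experiment left out and no experiment term for the flg22 response of a strain against the others. No gene met the stricter planned share of conditions or the set of falling genes, the smaller share gave the set already used, and no library was below the planned minimum of total counts, so these gave no value. Depth limits the calls, since at 1656231 counts per library the shares and medians listed with thinned counts were lower, except the median of strains for flg22.

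The share of genes called for flg22 without bacteria, 3.27%, became 1.33% with no experiment term, 1.83% with the replicate block, 1.16% without e1, 1.71% without e2 and 2.11% with thinned counts. With e.coli, 3.6% became 1.16% with no experiment term, 2.06% with the replicate block, 1.52% without e1, 0.724% without e2 and 1.86% with thinned counts. With HK-SynCom35, 0.0549% became 0.106% with no filter, 0% with no experiment term, 0.0183% with the replicate block, 0% in e3 alone, 0.818% in e2 alone, 0.170% with summed libraries, 0.0346% with thinned counts, 0.188% with DESeq2 and 4.17% without both HK-SynCom35 libraries. Leaving out 1 HK-SynCom35 library at a time moved it from 0% to 2.76%, with 2.76% without mock replicate 3 of e3 and 0.282% without flg22 replicate 3 of e3. It was 0 without mock e2 replicate 1, flg22 e2 replicate 2 or flg22 e3 replicate 2, 0.0186% without mock e2 replicate 2, 0.0122% without flg22 e3 replicate 1, 0.00618% without mock e2 replicate 3, 0.00610% without mock e3 replicate 1, 0.00608% without mock e3 replicate 2 and 0.00601% without flg22 e2 replicate 1. The median over strains, 1 gene, became 8 with no filter, 0 with no experiment term, 6 with the replicate block, 0.5 without e1, 15 without e3, 3.5 with summed libraries, 4.5 with thinned counts and 54.5 without the doubted e3 libraries. The average over strains, 27.7%, became 6.49% without e2.

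The share of genes whose response differed from No bacteria became, from 0.712% with SynCom35, 0.280% without e1, 0.259% without e2, 0.185% with summed libraries and 0.462% with thinned counts. From 0.304% with e.coli it became 0.0608% with no experiment term, 0.127% with the replicate block, 0% without e1, 0.0224% without e2, 0.168% with summed libraries and 0.130% with thinned counts. The median of 61.5 genes per strain became 27 with no experiment term, 15 without e1, 15.5 without e2, 7.5 with summed libraries and 30 with thinned counts.

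In mock against No bacteria, 7.38% with SynCom35 became 3.63% without e1, 4.53% without e2, 3.6% with summed libraries and 4.57% with thinned counts. For HK-SynCom35, 0 became 0.00559% with no experiment term, 0.0730% without e2, 0.212% without e3, 0.107% with summed libraries and 0.00555% without both HK-SynCom35 libraries. For e.coli, 4.81% became 1.46% with no experiment term, 2.37% without e2, 2.14% without e3, 2.72% with summed libraries and 3.61% with thinned counts. The median strain, 3.85%, became 1.7% with no experiment term, 1.16% without e1, 1.62% without e2, 0.853% with summed libraries, 2.21% with thinned counts and 6.36% without the doubted e3 libraries. Between SynCom35 and HK-SynCom35, 4.76% in mock became 0.915% with summed libraries and 3.14% with thinned counts, and 2.21% with flg22 became 1.46% with no experiment term, 1.19% in e3 alone, 0.882% in e2 alone, 0.457% with summed libraries and 1.57% with thinned counts. Their interaction, 0, became 0.0725% in e2 alone and 0.343% without both HK-SynCom35 libraries. Against the other strains, a median of 0.788% became 1.31% without the doubted e3 libraries, 1.39% without e1, 0.0963% without e2 and 0.474% with no experiment term, and the number of strains with their own response rose from 2 to 6 without the doubted e3 libraries.

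Of 37 conditions, the 31 with a smaller response on the planned genes, a count partly built in because AT2G41810 is used only in conditions that do not call it, became 19 without e3, 5 with the wider gene set, 0 with the wider set without e1, 2 with the wider set without e2, 3 with the wider set without e3 and 1 with the wider set without the doubted e3 libraries. Between e1 and e3, r moved from 0.252 to 0.589 without the doubted e3 libraries, and between e2 and e3 from 0.223 to 0.679. With the fixed list and without these libraries r was 0.522 between e2 and e3, from 0.124 with all, and 0.172 between e1 and e3, from -0.0674, and without No bacteria and MF2 0.206 and -0.339.

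Of 20 lists, the 11 that passed for flg22 without bacteria became 4 with an estimated correlation. With SynCom35, 0 became 6 without e1, 1 without e2 and 6 without e3. With HK-SynCom35 7, with e.coli 9 and in the average 12 each became 0 with an estimated correlation. In mock, 11 with SynCom35 became 6 with an estimated correlation, 5 with HK-SynCom35 became 1 with an estimated correlation and 11 without e3, 12 with e.coli became 3 with an estimated correlation and 10 between communities became 0 with an estimated correlation and 6 without e2. Of the list and condition pairs, 30% passed in mock, which became 0% without e1, 13.2% without e2 and 11.6% without e3, and 7.03% in response, which became 1.08% without e1, 1.22% without e2 and 3.51% without e3. With an experiment left out the exact test in mock has few assignments, so the mock pairs do not show which experiment matters. The response test reassigns both mock and flg22 libraries and has more assignments, so this limit does not cover the pairs lost in response. Replicate numbers did not pair libraries, with a median correlation of -0.00919 between mock and flg22 residuals and 0 of 38 conditions paired.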

Other observations

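The splits given here were planned before the results were seen, and the simulation of a shared control and the overlaps between comparisons after.

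Against the mean of the other strains in mock, called members of the lists were counted per strain, with no list test and no test between strains. Iron deficiency genes were higher in 16 of 21 members with MF40 and in 10 of 21 with MF33. With MF27, 6 of 21 iron deficiency genes and 6 of 20 flg22/PTI markers were lower. Salicylic acid genes were higher in 10 of 18 with MF41, and indole glucosinolate genes in 7 of 17 with MF370. Photosynthesis genes were higher in 12 of 20 with MF362 and lower in 9 of 20 with MF2. With MF161 7 of 12 aliphatic glucosinolate and 6 of 12 anthocyanin genes were lower and 6 of 9 auxin genes higher. With CL18 9 of 20 flg22/PTI markers were higher, and 5 without the doubted e3 libraries.

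Of the genes called in mock with SynCom35 against No bacteria, 24% were called in the same direction with e.coli and 0.700% in the opposite one. Of those also tested against HK-SynCom35 27.9% were called there in the same direction. These comparisons share the No bacteria or the SynCom35 mock libraries, which can raise such overlaps without a shared change, and no value without shared libraries was computed. With 1 shared control, the salicylic acid list was higher in 31 conditions at p under 0.05, against a simulated 95th percentile of 11 and 0 of 100 simulations as large. For the flg22/PTI list these values were 25, 17.05 and 1, for immune receptors 26, 16.1 and 3, for ethylene and defensins 22, 13 and 0, for iron deficiency 18, 24.05 and 15, for lower anthocyanin genes 12, 13.3 and 9, and for lower endodermis and suberin genes 14, 17 and 9. The counts for iron deficiency, anthocyanin and endodermis thus lay within what a chance deviation of the control gave.

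For flg22 against mock, 1 of 100 splits, the real one, reached the 3.27% without bacteria (highest other 1.15%). With e.coli the real split alone reached 3.6% (0.864%). Both lay at the smallest share that 100 splits can give. All splits moved single libraries within experiments, so they do not test variation between experiments. No adjustment was made over the comparisons. With SynCom35 the real value was 0 in edgeR, which all 100 splits reach whatever the data, so they decide nothing. There 3.92% of genes had an unadjusted p under 0.05, DESeq2 also called 0, and the highest other split gave 0.806%. With HK-SynCom35 5 of 100 reached 0.0549% (2.38%), so chance cannot be excluded for the libraries as labelled. These splits included the 2 HK-SynCom35 libraries of e3 that lay with the other treatment. Without both 4.17% of genes passed, a rise partly built in by how they were picked, and splits without them were not drawn. The highest other with SynCom35 lay below those without bacteria and with e.coli, and what raised the highest others was not tested. In mock against No bacteria 1 of 60 splits, the real one, reached 7.38% with SynCom35 (0.00560%) and 4.81% with e.coli (1.75%). This is the smallest share that 60 splits can give. With HK-SynCom35 the real value was 0 in edgeR, with 4.95% of genes at an unadjusted p under 0.05 and a highest other of 0.0112%, and as all 60 splits reach 0 whatever the data they decide nothing. Between SynCom35 and HK-SynCom35 1 of 60 reached 4.76% in mock (2.21%) and 2.21% with flg22 (0.0117%), again the smallest share possible.

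Over the strains 25 splits were drawn on subsets of genes. The real split alone reached the median share called for flg22, 0.05% of 3000 genes, and in mock against No bacteria, 3.83%, where the highest others were 0. It alone reached the average over strains, 24% of 300 genes (highest other 0.667%), and the share called over all strains against the other strains in mock, 5.38% of 300 genes (1.02%). These 4 results, each at 1 of 25, lay at the smallest share that 25 splits can give. That is under a share of 0.05 but too coarse to exclude chance. In mock against No bacteria the strains also share 1 control. For the flg22 response of a strain against the others 12 of 25 splits reached the real 0.471% of 100 genes (1.03%), and chance cannot be excluded.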
